A study of Mus musculus with 6 samples.

How the data were processed

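Total RNA, 300 ng per sample, from the left lung lobe of mice was labelled with biotin and hybridised to 1-colour Affymetrix arrays of the Mouse Gene 1.0 ST design, 1 array per sample, per the labels' protocols. There were 3 control lungs and 3 mucinous tumor lungs, grouped by their titles. The deposited values are log2 expression values per probe set that the authors made with RMA, which corrects background, normalizes between arrays and summarises probes, per the submitters' processing notes. No version of RMA is given in the sources used here. The base of the logarithm is not stated and was taken as 2, since RMA gives log2 values and the deposited values run from 3.04 to 14.0. The log2 values are relative levels without calls of detection, so a low value cannot be told from background, and changes of dim genes are understated. The array medians lay between 7.68 and 7.72.

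The value table held 35556 probe sets. The platform annotation gave exactly 1 gene symbol for 21789 of them and several for 1621, and it did not list 12146, which are unnamed here. Of the probe sets with 1 symbol, 21698 matched a RefSeq gene table (assembly GRCm38.p6, used for names only) by gene identifier, and 0 symbols changed. Probe sets with several symbols or none were left out of the main test. Where several probe sets shared a symbol (999 genes), the one with the highest mean over all arrays stood for the gene, which left 19938 genes. No genome build is named for the values, and no coordinates are given.

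The tumor and control groups were compared on the log2 values as deposited, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all 19938 genes). A gene was called at an adjusted p under 0.05, and a fold change of at least 2 was counted besides. Fold changes are differences of log2 group means. Lists of textbook marker and pathway genes were tested with camera from limma with a preset inter-gene correlation of 0.01, two-sided, adjusted over 33 lists of at least 5 measured genes. One further list, of sex-linked genes, was described and not tested. The member counts of a list used the adjustment over all genes, and a second count was adjusted over the list alone. Camera compares a list with the other genes. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were alternatives.

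The groups, the test, the 34 lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the manipulated genes, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, and up to 4 called members of each list with the largest change. A few other genes are named as picked afterwards. Kras was not analysed here.

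The test was run on simulated data with known answers, 20 sets of 19938 independent genes with the means and spreads of the real genes and 200 genes changed between tumor and control. At a log2 change of 0.5, 75.6% of the changed genes were recovered, at 1 the share was 96.3% and at 2 it was 99.3%, while 4.09% of the calls were false. With no list changed, the camera test called 0.05 lists per simulated set, but the simulated genes were independent, unlike real ones.

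The alternatives were a trended and robust variance prior, a filter that left out the dimmest 30% of genes, repeated quantile normalization, median centring, cyclic loess normalization, the mean of all probe sets of a gene, array weights, the replicate number as a block, all probe sets, a 2-fold minimum, and leaving out each array in turn. The 3 control lungs differ in genotype, so their spread includes any effect of genotype.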

Results

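Gene expression was measured in 6 left lung lobe samples from mice of a mixed C57BL/6, 129/Sv and FVB/N background, each on 1 microarray. The animals received doxycycline for 2 months and were taken at 3 months of age. The 3 tumor lungs came from mice with a doxycycline-dependent activator (Scgb1a1-rtTA) driven by the promoter of Scgb1a1. Scgb1a1 is a gene of club cells, the secretory cells of the airway. Which cells made the activator was not measured. The activator switches on mutant KRAS with the G12D change, on a background with 1 functional copy of Nkx2-1, the lung epithelial transcription factor. Such lungs develop mucinous tumors, and the stated purpose of the series was to find genes induced in them. The 3 control lungs had 3 different genotypes, namely the KRAS transgene without the activator, the activator without the KRAS transgene, and wild type. They form a group only as lungs without tumors. No listed control genotype joins the activator to the KRAS transgene, and none includes the loss of an Nkx2-1 copy. Effects of mutant KRAS, of Nkx2-1 copy number and of tumor tissue therefore cannot be told apart. The values are log2 expression values, and each array had a median between 7.68 and 7.72. The number of arrays limits the precision. Across the 19938 genes analysed, arrays of the same group correlated at r = 0.9956 to 0.9964 and arrays of different groups at r = 0.9789 to 0.9835, which are correlations across genes that are not independent replicates. The first principal component held 75.8% of the variance and put the 3 control arrays on one side and the 3 tumor arrays on the other. As the labels do not say how the samples relate to each other beyond genotype, p-values measure only the spread between these samples.

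The genes the mouse model manipulates came first. Nkx2-1 stood at 10.63 ± 0.36 (SD, n = 3) in the control lungs and 10.83 ± 0.07 in the tumor lungs, a difference of 0.20 (SE 0.15) that did not pass (limma adjusted p = 0.345). The control arrays read 10.43, 11.04 and 10.42 and the tumor arrays 10.80, 10.92 and 10.78, so the 2 groups overlapped. Without control array 2 the difference was 0.41 and passed (limma adjusted p = 0.00519). Scgb1a1, the secretoglobin whose promoter drives the activator, read 13.23, 13.19 and 13.19 in the control arrays and 13.26, 13.30 and 13.28 in the tumor arrays. Its difference of 0.07 (SE 0.05) did not pass (limma adjusted p = 0.252). These values lay near the top of the range, as the highest value of each array was between 13.73 and 14, and a difference there can be understated. Kras was not analysed here.

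Among genes that passed and had all 3 arrays of one group above all 3 of the other, Dmbt1, Ltf and Gp2 rose most in the tumor lungs, and Adgre4, Acoxl and Pon1 fell most. Dmbt1, a mucosal scavenger-receptor glycoprotein, was 72.2-fold higher, with a level of 6.14 ± 0.04 (SD, n = 3) in control and 12.31 ± 0.23 in tumor lungs (limma adjusted p = 6.68e-08). Ltf, which encodes the iron-binding protein lactoferrin, was 55.0-fold higher (limma adjusted p = 6.68e-08), Gp2 45.7-fold, the antibacterial lectin gene Reg3g 32.1-fold, and Agr2, a protein disulfide isomerase needed for mucin folding, 21.9-fold. The next in size were the trefoil peptide gene Tff2 (17.6-fold), the airway secretory genes Bpifb1 (14.4-fold) and Bpifa1 (10.7-fold), the junction gene Vsig1 (11.7-fold), the gel-forming mucin Muc5b (11.6-fold), the chitinase-like gene Chil4 (9.74-fold) and 2210407C18Rik (9.23-fold). Chil4 varied most among them, with an SD of 1.47 over the tumor lungs against 0.11 over the controls, and its near-identical relative Chil3 makes its own level uncertain. Without tumor array 3, which read 7.59, the log2 change of Chil4 was 4.13 in place of 3.28. The falls were smaller. The largest among genes without overlap were in Adgre4, a macrophage adhesion receptor (2.52-fold lower, limma adjusted p = 0.000315), Acoxl (2.34-fold), the paraoxonase gene Pon1 (2.24-fold), Myzap (2.22-fold), the carbonic anhydrase gene Car3 (2.18-fold), Edil3 (2.08-fold), the growth factor gene Bmp6 (2.06-fold), the endothelin receptor gene Ednrb (2.05-fold), Nkg7, a granule protein of cytotoxic lymphocytes (2.04-fold), Epb41l3 (2.03-fold), the inhibitory Smad gene Smad6 (1.99-fold) and the granzyme gene Gzma (1.97-fold). Ppbp, the platelet basic protein gene, also fell, by 2.37-fold (limma adjusted p = 0.0401), but its groups overlapped, and the call was lost without control array 1, control array 3, tumor array 1 or tumor array 2, with adjusted p up to 0.120.

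In all, 6193 of the 19938 genes passed (limma adjusted p under 0.05), 2642 of them higher and 3551 lower in the tumor lungs, so that 42.7% of the calls were higher. A change of at least 2-fold was found in 280 of the higher genes and in 11 of the lower ones, and a change of at least 4-fold in 45 and 0. Over the called genes the median size of the change was 0.30 on the log2 scale. The groups did not overlap in 49.2% of all genes, where chance gives 10%. The split between higher and lower depended on scaling, since cyclic loess normalization gave 2800 higher and 2262 lower (55.3% higher). Without tumor array 1 the count was 3801, and the 11 genes at least 2-fold lower became 23 without control array 2, 17 without control array 3 and 21 without tumor array 3.

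**Figure D1:**
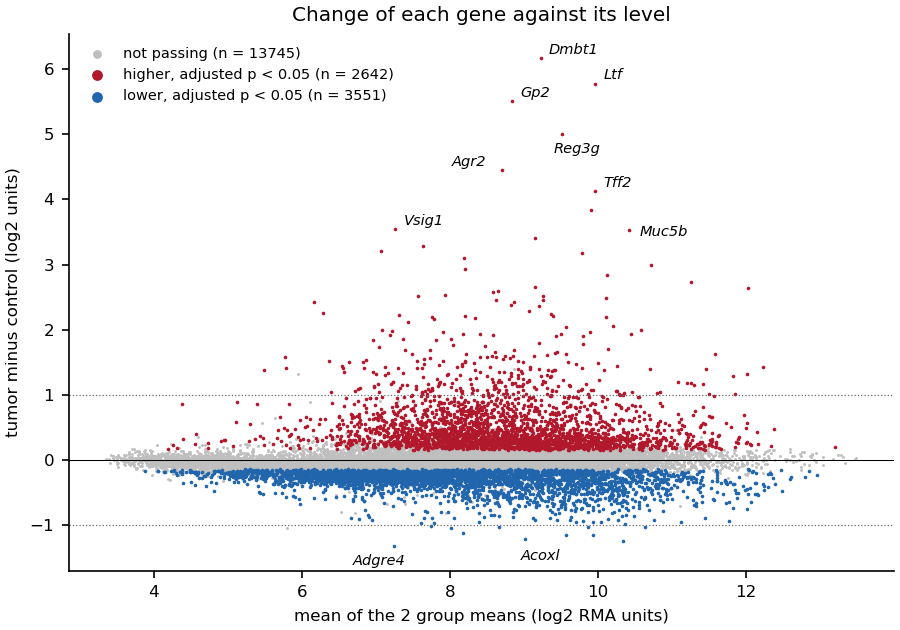
Each point is 1 of 19938 genes, with the mean of the control and tumor means on the horizontal axis (log2 RMA units) and tumor minus control on the vertical axis (log2 units). Red points were higher (2642) and blue points lower (3551) at a limma adjusted p under 0.05, grey points did not pass, and the dotted lines mark a 2-fold change, which 280 higher and 11 lower genes exceeded.

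Mucous-cell genes rose together. Of the 24 measured members of the goblet and mucous list, 20 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone, and the median change was 0.77 on the log2 scale. Agr2, Tff2, Bpifb1 and Muc5b led this list. Muc5ac, the other gel-forming airway mucin, rose 5.97-fold, from 7.29 ± 0.10 (SD, n = 3) to 9.86 ± 0.40 (limma adjusted p = 6.60e-05). Spdef and Foxa3, transcription factors of goblet cell differentiation, differed by 0.02 (adjusted p = 0.838) and 0.03 (adjusted p = 0.773). Muc5ac, Spdef and Foxa3 were picked from the list after their values were seen. The list shifted up (camera adjusted p = 1.25e-14, but adjusted p = 0.278 with an estimated correlation). In fits with fewer samples, the 20 risers became 15 without control array 2 or tumor array 1 and 16 without control array 3. They became 18 without control array 1 or tumor array 2, and stayed 20 without tumor array 3. The 1 faller was lost without control array 1 or 3 or tumor array 1 or 3.

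Genes of the stomach and intestine went both ways. Of 27 measured members, 11 rose, 5 fell and 11 did not pass (11 rose and 9 fell adjusted over the list alone). Vsig1, Anxa10 (4.68-fold, limma adjusted p = 4.48e-05), the keratin gene Krt20 (4.33-fold) and the galectin gene Lgals4 (3.81-fold) led the rises. Among the fallers were Cdx2 and Gata4, transcription factors of the intestine and foregut, with changes of -0.24 each on the log2 scale (limma adjusted p = 0.0453 and 0.0125), picked after their values were seen. The Cdx2 call was lost without control array 2, control array 3, tumor array 1 or tumor array 2, with adjusted p up to 0.131. The list's 5 fallers became 2 without control array 3 or tumor array 1, and 3 without control array 2 or tumor array 2 or 3. The list median was 0.03 and its mean 0.50, and the list shifted up (camera adjusted p = 0.0135, but adjusted p = 0.382 with an estimated correlation).

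Genes of epithelial defence, such as antimicrobial and acute-phase proteins, rose in 17 of 28 measured members, while 1 fell and 10 did not pass, with the same counts adjusted over the list alone. Besides Ltf, Reg3g, Bpifb1 and Bpifa1, 8 further members were at least 2-fold higher, and the list median was 0.61 (camera adjusted p = 2.90e-09, but adjusted p = 0.170 with an estimated correlation). The Reg and Bpif genes belong to families of similar sequence, so values of single members are uncertain. The 1 faller was lost without control array 2 or 3 or tumor array 3.

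**Figure D2:**
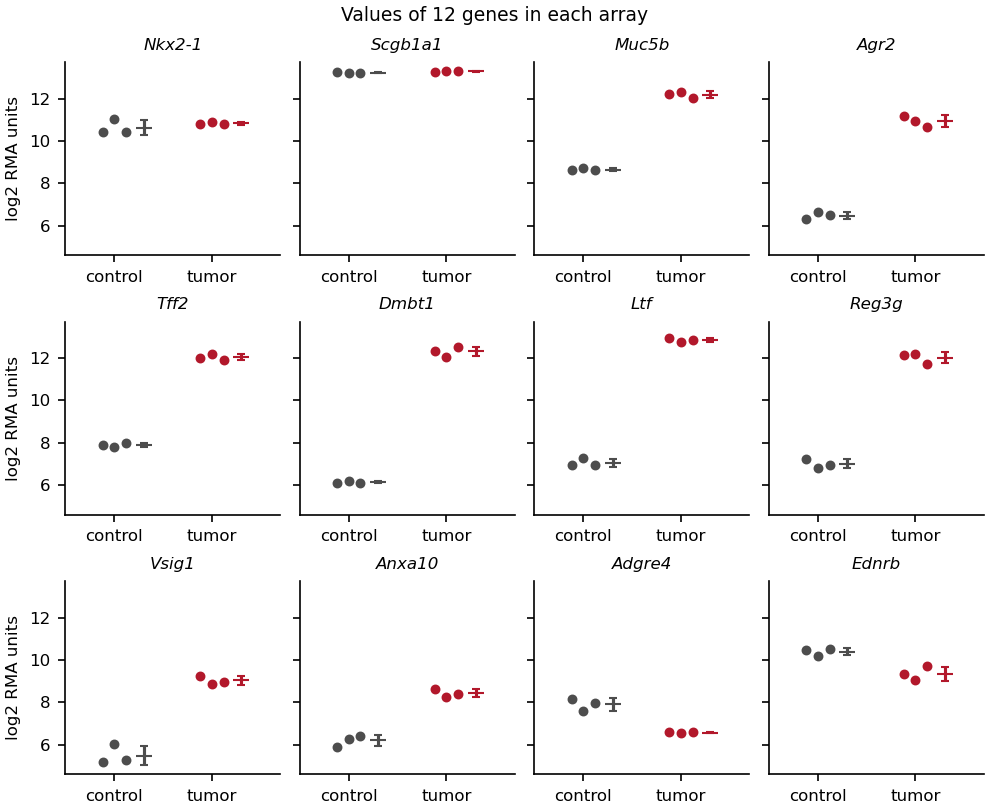
Log2 RMA values of 12 genes, with 1 point per array for the 3 control lungs (grey) and the 3 tumor lungs (red), and the group mean ± SD beside the points. Nkx2-1 overlapped between the groups. Scgb1a1 read 13.19 to 13.30, near the top of the range. Its tumor arrays all lay above the controls, but the mean difference of 0.07 did not pass. The 8 genes from Muc5b to Anxa10 also lay above the controls in all 3 tumor arrays, and Adgre4 and Ednrb lay below.

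Genes of ciliated and club cells were mostly higher. Of the 25 genes of ciliated cells, 21 rose, 0 fell and 4 did not pass, with the same counts adjusted over the list alone. The cadherin-like gene Cdhr4 rose 3.43-fold (limma adjusted p = 6.77e-05), Sntn 3.15-fold, the radial spoke gene Rsph4a 2.36-fold and the dynein light chain gene Dynlrb2 2.19-fold, and the list median was 0.79 (camera adjusted p = 1.50e-15, but adjusted p = 0.278 with an estimated correlation). Of 19 club cell genes, 13 rose, 3 fell and 3 did not pass (13 rose and 4 fell adjusted over the list alone), with a median of 0.61 (camera adjusted p = 3.99e-06, but adjusted p = 0.278 with an estimated correlation). Retnla rose 7.98-fold, the secretoglobin Scgb3a1 6.22-fold (limma adjusted p = 4.13e-06), Gsto1 3.81-fold and Chad 3.73-fold, whereas Pon1 was the club cell member that fell most. The tumor values of Scgb3a1, 13.30 to 13.41, lay near the top of the range, where a rise can be understated. The 3 club cell fallers became 1 without control array 3 or tumor array 1. Of 14 basal and squamous genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone). Trp63, the basal cell transcription factor, rose 2.09-fold (limma adjusted p = 0.000171) and Sprr1a 1.87-fold, but the list as a whole did not pass (camera adjusted p = 0.270), its median being -0.02 and its mean 0.21. The 1 faller became 2 without control array 1 and 0 without control array 2 or 3 or tumor array 1 or 2. Of 13 neuroendocrine genes, 1 rose and 2 fell, with the same counts adjusted over the list alone, and the synaptic vesicle gene Syp was 1.20-fold lower (camera adjusted p = 0.720 for the list). The neuroendocrine riser was lost without control array 3 or tumor array 1, and the 2 fallers became 1 without control array 2 or tumor array 2.

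Of 20 genes of alveolar type 1 cells, the flat gas-exchange cells, 12 fell, 2 rose and 6 did not pass (12 fell and 3 rose adjusted over the list alone). Rtkn2 fell 1.44-fold (limma adjusted p = 0.00543), and Sema3e and Pdpn each 1.36-fold, whereas the keratin gene Krt7 rose 1.45-fold. The list median was -0.26 (camera adjusted p = 0.0363, but adjusted p = 0.684 with an estimated correlation). That call was lost without control array 1 (adjusted p = 0.0951), control array 3 (0.0578) or tumor array 2 (0.107), and with fry (0.0782). Of 21 genes of alveolar type 2 cells, which make surfactant, 6 rose, 1 fell and 14 did not pass, with the same counts adjusted over the list alone. The phospholipase gene Pla2g1b rose 2.07-fold (limma adjusted p = 0.001) and the mucin Muc1 1.61-fold. The list median was 0.05 (camera adjusted p = 0.0499, but adjusted p = 0.484 with an estimated correlation), and the call was lost without control array 1 (adjusted p = 0.134) or tumor array 3 (0.143), with fry (0.0630), with the filter on dim genes (0.173), with repeated quantile normalization (0.0918) and with cyclic loess (0.323). Its 6 risers became 3 without tumor array 1 or 3, and its 1 faller became 2 without control array 1 or tumor array 3.

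Endothelial genes were mostly lower in the tumor lungs. Of 26 endothelial genes, 21 fell, 0 rose and 5 did not pass (22 fell adjusted over the list alone). The median was -0.56 on the log2 scale (camera adjusted p = 8.55e-10, but adjusted p = 0.285 with an estimated correlation). Ednrb fell 2.05-fold, Plvap, a protein of endothelial fenestrae, 1.95-fold, Ramp2 1.86-fold and Kdr, the main VEGF receptor gene, 1.73-fold (limma adjusted p = 0.000183). Genes of cardiac muscle, which in mice also surrounds the pulmonary veins, fell in 16 of 17 members, with the same count adjusted over the list alone. Myh6 was 1.55-fold and Actc1 1.44-fold lower, and the list median was -0.47 (camera adjusted p = 2.81e-05, but adjusted p = 0.401 with an estimated correlation). The 16 fallers became 9 without control array 3 or tumor array 1, and 10 without control array 2 or tumor array 2 or 3. All 7 measured genes of red cells and platelets fell, also adjusted over the list alone, among them the platelet integrin gene Itga2b at 1.48-fold lower (camera adjusted p = 0.00546 for the list, but adjusted p = 0.401 with an estimated correlation). These 7 fallers became 3 without control array 1, 2 without control array 3 or tumor array 1, and 4 without tumor array 3. Of 15 smooth muscle genes, 4 fell and 11 did not pass (7 fell adjusted over the list alone), including Mylk, the myosin light chain kinase, at 1.36-fold lower. That list shifted down (camera adjusted p = 0.00977, but adjusted p = 0.550 with an estimated correlation), a call lost without control array 3 (adjusted p = 0.0542) and with fry (0.0630).

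Genes of fibroblasts and matrix rose in 13 of 26 members, while 5 fell and 8 did not pass (13 rose and 6 fell adjusted over the list alone). Timp1, an inhibitor of metalloproteinases, rose 2.54-fold (limma adjusted p = 0.000332), the collagen and elastin cross-linking enzyme gene Lox 2.11-fold, elastin (Eln) 2.00-fold and tenascin C (Tnc) 1.65-fold. The median was 0.13 (camera adjusted p = 0.00641, but adjusted p = 0.278 with an estimated correlation), and the filter on dim genes ended the call (adjusted p = 0.105). The 13 risers became 8 without tumor array 3, and the 5 fallers became 2 without control array 2 or 3, 1 without tumor array 1 or 2, and 3 without tumor array 3. Of 11 adipose genes, 6 fell and 1 rose, with the same counts adjusted over the list alone. Car3 was 2.18-fold and Plin1 1.29-fold lower, whereas Cidea, a lipid droplet gene, was 1.78-fold higher (limma adjusted p = 6.81e-05). The adipose list did not pass (camera adjusted p = 0.0755), although it passed with the filter on dim genes (adjusted p = 0.0199), with fry (0.00992) and without tumor array 3 (0.0492).

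Of 23 genes of T and NK cells, 11 fell, 0 rose and 12 did not pass (15 fell adjusted over the list alone). Nkg7 and Gzma led, the NK cell receptor gene Ncr1 fell 1.84-fold (limma adjusted p = 0.00153) and Cd2 fell 1.52-fold, and the list shifted down (camera adjusted p = 0.00114, but adjusted p = 0.541 with an estimated correlation). Of 17 B and plasma cell genes, 4 fell and 2 rose (5 and 2 adjusted over the list alone). The kinase gene Blk was 1.35-fold lower (limma adjusted p = 0.0114). Jchain, the joining chain of secreted antibody polymers, was 5.71-fold higher, from 8.0 ± 1.5 (SD, n = 3) to 10.51 ± 0.41 (limma adjusted p = 0.0211), a call lost without control array 1, tumor array 1 or tumor array 2, with adjusted p up to 0.0659. Its log2 change of 2.51 became 3.31 without control array 2 and 1.82 without control array 3. The list as a whole did not pass (camera adjusted p = 0.362). Its 4 fallers became 1 without tumor array 1 or 3 and 2 without tumor array 2, and its 2 risers became 0 without control array 1 or tumor array 1 or 2, and 1 without control array 3 or tumor array 3. Of 20 genes of antigen presentation and dendritic cells, 5 fell and 0 rose, also adjusted over the list alone, with Clec9a at 1.32-fold and Zbtb46 at 1.31-fold lower (camera adjusted p = 0.287 for the list, fry adjusted p = 0.0187), and 1 rose without control array 3. Of 9 thymocyte genes, 3 fell and 1 rose (5 and 1 adjusted over the list alone). The riser was Ly6d, which is also made by epithelial cells, at 4.63-fold higher (limma adjusted p = 0.000116), and the list did not pass (camera adjusted p = 0.270), its median being -0.16 and its mean 0.07. The 3 thymocyte fallers became 1 without control array 2 or tumor array 1.

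Myeloid genes were mixed. In the list of recruited macrophages 8 of 24 genes rose, 1 fell and 15 did not pass, with the same counts adjusted over the list alone. The macrophage elastase gene Mmp12 rose 1.96-fold (limma adjusted p = 0.00106) and Lgals3 1.52-fold, and the list shifted up (camera adjusted p = 0.00235, but adjusted p = 0.278 with an estimated correlation). The 8 risers became 5 without control array 1 or 3 or tumor array 2, and 4 without tumor array 3, and the 1 faller became 2 without control array 2. Of 21 genes of alveolar macrophages, 5 rose and 6 fell (6 and 7 adjusted over the list alone), with Ctsk 2.19-fold and Plet1 1.57-fold higher and Car4 1.57-fold lower (camera adjusted p = 0.753 for the list), and the 5 risers became 3 without tumor array 2 or 3. Of 20 neutrophil genes, 4 rose and 7 fell (4 and 8 adjusted over the list alone). The leading risers were Ltf, Pglyrp1 (3.90-fold) and Cd177 (2.67-fold), secreted or surface proteins that epithelia can also make, whereas Hdc, the histamine-forming enzyme, was 1.90-fold lower (limma adjusted p = 0.011). The neutrophil list did not pass with camera (adjusted p = 0.907, direction down), its median was -0.13 and its mean 0.31, and fry, which asks whether the genes move one way on balance, gave an upward shift (adjusted p = 0.00674). The 7 neutrophil fallers became 4 without control array 1 or 3 or tumor array 1 or 2. Of 18 genes of mast cells, basophils and eosinophils, 6 rose and 4 fell (6 and 5 adjusted over the list alone). The mast cell carboxypeptidase Cpa3 rose 2.16-fold (limma adjusted p = 0.00488), and Mcpt2 and Mcpt1, near-identical protease genes whose probes may share signal, read 5.39-fold and 2.60-fold higher, while Kit fell 1.80-fold (camera adjusted p = 0.588 for the list). Of 33 chemokine and cytokine genes, 6 rose and 3 fell, with the same counts adjusted over the list alone, led by Ccl17 at 1.94-fold higher (limma adjusted p = 0.0147, camera adjusted p = 0.513 for the list). The 6 risers became 3 without tumor array 1 or 3, and the 3 fallers became 1 without control array 3 or tumor array 1 or 3.

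Among signalling and metabolic lists, 4 shifted up. Of 31 proliferation genes, 7 rose and 1 fell (5 and 0 adjusted over the list alone), with Top2a 1.33-fold (limma adjusted p = 0.00644) and Cdk1 1.31-fold higher (camera adjusted p = 0.00235, but adjusted p = 0.541 with an estimated correlation). The filter on dim genes (adjusted p = 0.105) and fry (0.193) ended that call. The 7 risers became 3 without control array 1 or tumor array 1 or 3, and 4 without control array 2 or 3, and the 1 faller was lost without control array 1 or 2 or tumor array 2. Of 23 genes of hypoxia and glycolysis, 11 rose and 3 fell (11 and 4 adjusted over the list alone), among them the prolyl hydroxylase gene Egln3 (2.70-fold), Pfkl (1.63-fold) and Ldha (1.59-fold, limma adjusted p = 0.000480), with camera adjusted p = 0.00198 for the list but adjusted p = 0.401 with an estimated correlation. Of 22 genes of secretory load on the endoplasmic reticulum, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with Sdf2l1 1.28-fold and Creld2 1.27-fold higher (camera adjusted p = 0.00187, but adjusted p = 0.278 with an estimated correlation). These 5 risers became 3 without control array 1 or 2 or tumor array 2 or 3. Of 21 genes of the NRF2 response and xenobiotic metabolism, 10 rose and 3 fell (12 and 4 adjusted over the list alone). Malic enzyme (Me1) rose 2.81-fold, the glutathione transferase gene Gsta4 2.28-fold (limma adjusted p = 2.36e-05) and the cystine transporter gene Slc7a11 1.93-fold, with camera adjusted p = 0.00140 for the list but adjusted p = 0.401 with an estimated correlation. The 3 fallers of this list became 1 without control array 3 or tumor array 1. 

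Of 24 genes of RAS and MAPK output, 5 rose and 3 fell (6 and 3 adjusted over the list alone). The growth factor gene Ereg rose 3.21-fold (limma adjusted p = 6.77e-05), followed by Etv1 (1.32-fold), Phlda1 (1.31-fold) and Ccnd1 (1.29-fold), and the list did not pass (camera adjusted p = 0.0897). Its 3 fallers became 1 without control array 1 or 2 or tumor array 1 or 2. Of 21 cholesterol and fatty acid genes, 2 rose and 1 fell (2 and 0 adjusted over the list alone), and Me1 was the leading member (camera adjusted p = 0.965 for the list). Its 2 risers became 1 without control array 1 or 3 or tumor array 1 or 2, and 4 without control array 2. Its 1 faller became 2 without control array 1, and 0 without control array 2 or 3 or tumor array 1 or 2. Of 20 interferon genes, 1 rose and 5 fell, with the same counts adjusted over the list alone. Mx1 was 1.57-fold higher and its relative Mx2 1.39-fold lower (camera adjusted p = 0.412 for the list, and 0.0453 without tumor array 2). The 5 fallers became 3 without control array 1 or tumor array 3, 2 without control array 3, and 8 without tumor array 2. Of 21 immediate early and heat shock genes, 2 rose and 6 fell (2 and 7 adjusted over the list alone), with Nr4a1 1.55-fold and Jun 1.44-fold lower (limma adjusted p = 0.00136 for Jun, camera adjusted p = 0.286 for the list), and the 2 risers became 1 without control array 1 or 2 or tumor array 1 or 3. Of 16 circadian genes, 2 rose and 5 fell, with the same counts adjusted over the list alone. Bhlhe40 was 1.6-fold higher, and Hlf and Nr1d1 were 1.56-fold and 1.51-fold lower (camera adjusted p = 0.268 for the list). Of the 4 measured sex-linked genes, which were not tested as a list, 2 rose and 0 fell. Kdm5d was 1.22-fold higher in the tumor lungs (limma adjusted p = 0.0167, or 0.0600 without tumor array 1). Eif2s3y also passed (limma adjusted p = 0.0418), but kept its call in only 1 of the 6 fits without 1 array.

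In all, 18 of 33 lists passed with camera, 12 up and 6 down, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.170 and 4 lists had an unadjusted p under 0.05. By fry, 17 lists moved one way on balance.

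**Figure D3:**
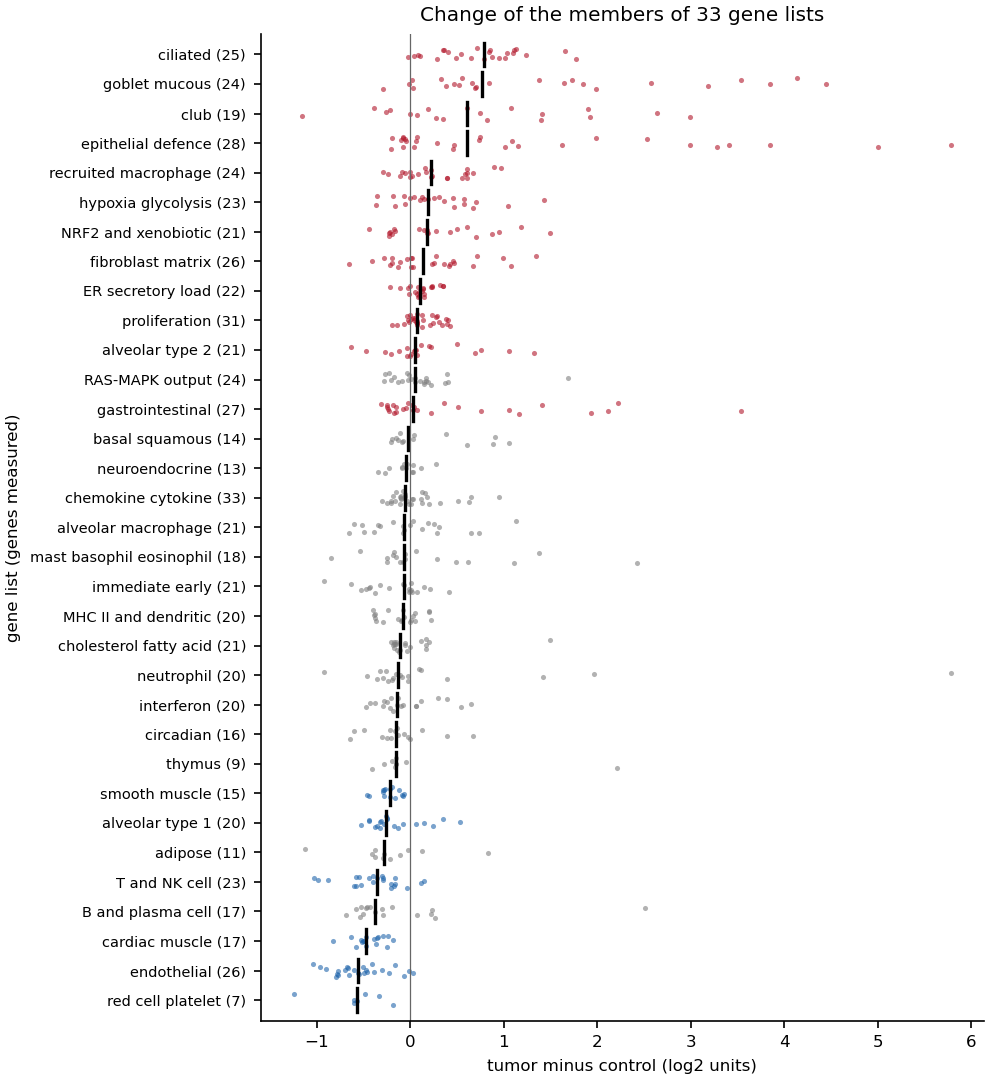
Each row is 1 of 33 gene lists, with the number of measured genes in brackets. Each point is 1 gene at its tumor minus control difference (log2 units), and the black bar is the list median. Red lists shifted up (12) and blue lists down (6) at a camera adjusted p under 0.05, and the medians run from -0.56 for red cells and platelets to 0.79 for ciliated cells.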

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

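No test in this part was chosen after the results were seen. The count of 6193 changed genes lay between 5062 and 6525 in the fits on all arrays that changed the prior, scaling, filter, probe set rule or weights, and between 3801 and 5067 when 1 array was left out (lowest without tumor array 1, with fewer samples). A 2-fold minimum left 291. Genes at least 2-fold lower numbered 8 to 23 without 1 array, and the cause was not tested. Of 33 lists, 18 passed as designed, 16 to 18 without 1 array, and 0 passed with an estimated correlation. The estimates for the 18 called lists ran from 0.0232 (epithelial defence) to 0.6404 (alveolar type 1), all above the preset 0.01. They were 0.4159 for ciliated, 0.3183 for goblet and mucous and 0.3082 for endothelial genes. The list calls and their small camera p-values therefore depend on the preset correlation. Why lists with estimates near the preset also lost their calls was not tested. The replicate numbers were not taken to pair the samples, since the deviations of same-numbered arrays correlated at 0.15, 0.16 and 0.03, the last under 0.1. A shared factor is not excluded, as each array correlated best with its own number and same-numbered arrays lay near each other on the second principal component (7.71% of the variance). With the replicate block 6300 genes and 17 lists passed, and the type 1 list lost its call (adjusted p = 0.0570). Of 143 named genes, 109 kept direction and side of the threshold in all alternatives that held them, and none reversed. The filter on dim genes held only 128 of the 143. Of the 141 called ones, 33 lost their call without at least 1 array.

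The direction of 5 uncalled lists turned, for causes not tested. Alveolar macrophage adjusted p was 0.979 with the dim filter, 0.972 with cyclic loess, 0.812 with fry and 0.441 to 0.862 without 1 array. Neutrophil adjusted p was 0.551 with the dim filter, 0.760 after repeated quantile normalization, 0.00674 with fry and 0.612 to 0.983 without 1 array. Neuroendocrine adjusted p was 0.778 after quantile normalization, 0.597 with cyclic loess and 0.538 to 0.995 without 1 array. Chemokine adjusted p was 0.968 with fry, and cholesterol adjusted p was 0.616 to 0.886 without 1 array. Without detection calls, how far signal over background limits dim genes is unknown.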

Other observations

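The tests of gene sets and explanations in this part were chosen after the results were seen, except the counts over other splits of the arrays, and several of these tests and their bounds were revised once after first values were known. Of 27 measured pan-epithelial genes 24 rose, 0 fell and 3 did not pass (Cgn, Myo5b and Ovol1), and the list shifted up (camera adjusted p = 3.71e-21, and 0.0369 with an estimated correlation, over 6 lists written after the results were seen). Its mean rise was 0.79 (SE 0.04) on the log2 scale, with the transcription factor genes Ehf 4.10-fold and Elf3 3.46-fold higher, Krt18 2.63-fold and Epcam 2.18-fold (limma adjusted p = 3.02e-06 for Ehf and 8.28e-05 for Epcam). Krt18, which had already been seen, was kept in the test of this list, so that test is not independent of these data. Enzymes that build mucin sugar chains rose in 11 of 25 measured genes and fell in 2 (1 without control array 3 or any 1 tumor array), led by St8sia6 (5.47-fold), Fut2 (5.35-fold) and Galnt3 (2.35-fold). Without those 3 genes, which had been seen before the list was written, the list still shifted up (camera adjusted p = 0.00280, and 0.0577 with an estimated correlation). Genes of injured or regenerating epithelium rose in 14 of 17 and fell in 1, among the risers Clu (6.67-fold), Tnip3 (2.83-fold), Krt8 (2.01-fold) and S100a6 (1.81-fold). The faller was Plaur, with a change of -0.28 on the log2 scale (limma adjusted p = 0.0352), a call that was lost without 1 array (adjusted p = 0.0529 to 0.0945) unless that was control array 3 (0.0226). The 8 members not seen before shifted up too (camera adjusted p = 2.85e-07, and 0.0298 with an estimated correlation), although 3 of those 8 (Krt8, Krt19 and Cldn4) are also in the pan-epithelial list.

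Genes of rarer epithelial cells gave less. Over 17 tuft cell genes the mean change was 0.00 (95% interval -0.07 to 0.08, camera adjusted p = 0.981), although Dclk1 alone rose by 0.90. The 10 M cell genes other than Gp2 and Pglyrp1 did not pass (camera adjusted p = 0.214), with 4 risen and 1 fallen. The 95% interval of their mean change lay above 0, with a lower bound of 0.02 and an upper bound of 0.19. The ionocyte genes other than Atp6v1b1 did not pass either (camera adjusted p = 0.802, lower bound -0.09, upper bound 0.17). Against a bound of 0.1 on the mean change only the tuft list of these 3 lay below, and against the bound of 0.2 first set all 3 did, so a small gain of M cells or ionocytes stays open. Gp2 itself, an M cell marker, was 45.7-fold higher, while the mean change of those other M cell genes was 0.10 (SE 0.04).

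Nkx2-1 had 1 functional copy in the tumor lungs, yet its transcript read 0.20 (SE 0.15) higher on the log2 scale, which did not pass with all arrays but did at 0.41 without control array 2 (limma adjusted p = 0.00519). An array that hides a halving is argued against, since the lower 95% bound of the change without any 1 array was at lowest -0.29, where a halving is -1. More epithelium per lung may offset a lower level per cell. This would need a rise of the expressing cells by 1.20 (95% interval 0.84 to 1.56). The pan-epithelial rise had an upper bound of 0.89, inside that interval, so the 2 cannot be told apart. That overlap rests on control array 2, the only control lung of its genotype. Without it the rise needed was 1.41 (95% interval 1.25 to 1.56), above the upper bound of 0.93 on the pan-epithelial rise in the same arrays. Which cells express Nkx2-1 was not measured, so the pan-epithelial genes only stand in for them. The mean change was 0.16 (95% interval 0.03 to 0.29) for alveolar type 2 genes, -0.16 for type 1 genes and 0.76 (0.62 to 0.90) for club cell genes. Among these lists only the club cell interval reached the range needed with all arrays. That interval is not given without control array 2, where the range needed began at 1.25. Higher output of the remaining copy is an untested alternative.

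Rises were larger and more frequent than falls at 2-fold, 280 genes against 11. The choice among 4 scalings does not account for it, since at most 14 genes were 2-fold lower under any of them. All 4 bring the arrays to a common level, so a shift of most genes together would not be seen. Dilution of normal lung by added tumor tissue would lower all genes of a normal cell type alike only under 2 conditions. No other cells may make them, and the arrays must respond evenly. The changes of the 19 endothelial genes with a mean above 10 ran from -0.96 to 0.03, with an SD of 0.27 against a median SE of 0.07. Of these genes, 11 lay more than 2 SE from their median, so they did not fall by 1 common amount. The limit to a mean above 10 was set after first values were seen. As the conditions were not tested, dilution as the whole or a part of the endothelial fall, loss of vessels and lower expression per cell stay open. As for the grouping, 1 of the 10 splits of the 6 arrays, the real one, gave as many as 6193 genes, and the highest other split gave 1. For genes at least 2-fold changed the values were 291 and 1, again in 1 split. For lists the real split gave 18, again the only split with as many. The other splits gave 8 to 16 lists, although they called at most 1 gene. Every other split still holds part of the tumor difference, and whether that gave these list calls was not tested. The count of lists called with the preset correlation therefore sets the real split apart only narrowly. With 10 splits no share under 0.05 is possible.

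Of 11 immunoglobulin genes 8 rose, 0 fell and 3 did not pass (4 rose without control array 1, 3 without control array 3 and 5 without tumor array 1), and of 15 B cell genes 0 rose, 5 fell and 10 did not pass (1 fell without tumor array 1 or 3, and 2 without tumor array 2). The mean immunoglobulin rise was 1.46 (95% interval 0.69 to 2.23), with Igha 7.13-fold and Ighm 3.08-fold higher (limma adjusted p = 0.00379 and 0.00545), and Ig variable genes are too similar for single values to be certain. Lymph node or follicle tissue caught with the lung would bring B cell genes, whose mean change was -0.42 with an upper 95% bound of -0.0125, or -0.22 without control array 1, and the upper bound was at most 0.10 without any 1 array. A single tumor lung as the source is argued against, since the mean rise without any 1 tumor array was at least 1.26. No biological explanation was tested.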
